A study of Mus musculus with 19 samples.

How the data were processed

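RNA of 19 libraries of sorted lin- Sca+ cKit+ cells was analysed, grouped by the labels as WT (4), IDH2-FLT3 vehicle (3), AG-221 (4), TET2-FLT3 vehicle (4) and 5-Aza (4). Per the labels' protocols the cells were primary and uncultured, polyA RNA was made into libraries with the SMARTer Ultra Low Input kit, AG-221 was given by gavage 2 times a day at 100 mg/kg alone or 40 mg/kg in combination for 4 to 5 weeks, and 5-Aza was injected at 5 mg/kg on 5 days of each 21-day cycle for 4 cycles. The labels do not give the AG-221 dose of each library, and the series text also names decitabine for the hypomethylating drug. Per the submitters' processing notes, the authors aligned reads to mm9 with STAR 2.4.0f1 and counted them with featureCounts of Subread 1.4.5-p1. The deposited count table holds raw counts per RefSeq accession, and the deposited FPKM table holds FPKM per accession, which matched the counts, the library totals and the accession lengths when recomputed. Columns were joined to groups by their headers and the labels' titles.

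The table has 33862 accessions, 33485 named from a RefSeq table and 188 from GENCODE; 189 without a name held 3.47% of counts. Genes with several accessions (5140 genes, 14603 accessions) lost reads: 61.6% of their accessions had 0 counts in every library against 18.9% of others, and 1392 such genes had none at all. No 2 libraries were copies of each other (lowest chi-square per gene 14.9).

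Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the 5 groups kept 11830 accessions, TMM factors ran from 0.761 to 1.22, and a quasi-likelihood fit of 5 group means to all 19 libraries had 14 residual degrees of freedom and a common dispersion of 0.184. Genes past a Benjamini-Hochberg adjusted p of 0.05 were called. The 7 pairs of groups and the difference of drug responses (AG-221 minus vehicle less 5-Aza minus vehicle) were the comparisons. CPM used library totals multiplied by the TMM factors. A group with 0 counts is bounded by 3 counts over its libraries, and the fold against it is a lower bound.

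Lists were fixed from general knowledge before the data were examined, 33 in all, of which 32 had at least 5 tested members; histone genes did not. They cover 12 cell types (stem, lymphoid-primed, granulocyte-monocyte, neutrophil, monocyte, dendritic, megakaryocyte, erythroid, mast, B, T/NK, endothelial), cell cycle (S, G2/M), interferon, MHC class I and II, germline and imprinted genes, DNA methylation machinery, STAT5 and MAPK targets, hematopoietic transcription factors, Hox genes, p53 targets, hypoxia, respiratory chain, unfolded protein, immediate-early, NF-kB, ribosomal and heme genes. Of 990 listed genes, 726 were tested. Each list was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM, adjusted over the lists, and also with an estimated correlation, with ranks and with fry.

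The rule for named genes took fixed targets that included Idh2, Flt3, Tet2, Dnmt1, Gata1, Gata2, Socs2 and Id1, and the 8 largest positive and negative log2 fold changes of called genes with a mean of 5 CPM and no overlap between the groups. Predicted genes, small RNA genes, Y-linked genes and Xist were left out. It also took up to 4 members with the smallest p of each called list, and the 4 smallest p per direction for the difference of drug responses. It named more genes than the text holds, and the 123 printed were chosen from them after their values were seen.

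In simulated data with the same depths and spread, changes of 2, 4 and 8 times were found in 4.48%, 56.7% and 72.7% of genes for AG-221 against vehicle, 5.97%, 56.7% and 84.8% for 5-Aza against vehicle and 8.96%, 56.7% and 77.3% for TET2-FLT3 vehicle against WT, with 2, 6 and 4 false calls among 11630 unchanged genes, so most 2-fold changes are missed.

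Other settings tried were RLE factors, no filter, a stricter filter (CPM of 5 in 3 libraries), a fit of the compared groups alone, DESeq2 1.42.0, limma-voom with quality weights, limma-trend on log2 FPKM plus 1 or 0.1, a fold minimum, and each library left out; those about V3-2 and V5-2 were added after the data were seen. Leukemia signatures that share WT, and drug responses that share vehicle libraries, were compared with 20 simulated data sets without an effect and with the shared group split 2 and 2. Every split of the libraries into groups of the same sizes was tested, or 100 random ones for the difference of drug responses. Transcript isoforms and variants at the engineered loci were not analysed here.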

Results

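Expression was compared across 19 RNA libraries of lin- Sca+ cKit+ cells, the compartment of hematopoietic stem and early progenitor cells, sorted from C57BL/6 mice. Wild-type (WT) mice gave 4 libraries. Leukemic Idh2 R140Q;Flt3-ITD mice gave 3 libraries with vehicle (IDH2-FLT3 vehicle) and 4 with AG-221, an inhibitor of mutant IDH2. Leukemic Tet2-/-;Flt3-ITD mice gave 4 libraries with vehicle (TET2-FLT3 vehicle) and 4 with 5-azacytidine (5-Aza), a hypomethylating drug. Assigned counts per library, in units of 1e6, ran from 10.2 to 12.3 in WT and 13.1 to 20.1 in IDH2-FLT3 vehicle. They ran from 9.91 to 11.99 with AG-221, 9.64 to 20.38 in TET2-FLT3 vehicle and 12.1 to 13.1 with 5-Aza. Levels are given as mean ± SD of counts per 1e6 counts (CPM), and log2 fold changes as estimate ± standard error. A gene is said to rise or fall where its adjusted p was under 0.05. The p itself is printed for the first genes of each comparison and for genes that did not pass. A dagger marks a call that ended when some single library of its comparison was left out, with the highest adjusted p this gave, and a double dagger one that ended only under another setting. Members of a list are those tested, and counts for the list alone are adjusted over the list instead of over all genes. The adjusted p of a list is given with a preset and then with an estimated correlation of its genes. Of 33862 accessions, 11830 passed the expression filter, with a biological coefficient of variation of 42.9%. The p-values measure the spread between these libraries, because the labels do not say that each came from a separate animal. Bounds given for groups with 0 counts cover counting error.

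The first 2 principal components held 27.3% and 18.3% of the variance. WT libraries lay together, V3-2 and V3 of IDH2-FLT3 vehicle lay furthest from them on the first component, and V1 of TET2-FLT3 vehicle on the second. Vehicle libraries V3-2 and V5-2 also differed from V3 and V5 in composition. The ribosomal RNA precursor Rn45s took 0.808% and 0.866% of their counts, against 2.39% and 2.63% in V3 and V5. V1 held 9.50% Rn45s and detected 12088 accessions, the fewest of all.

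**Figure D1:**
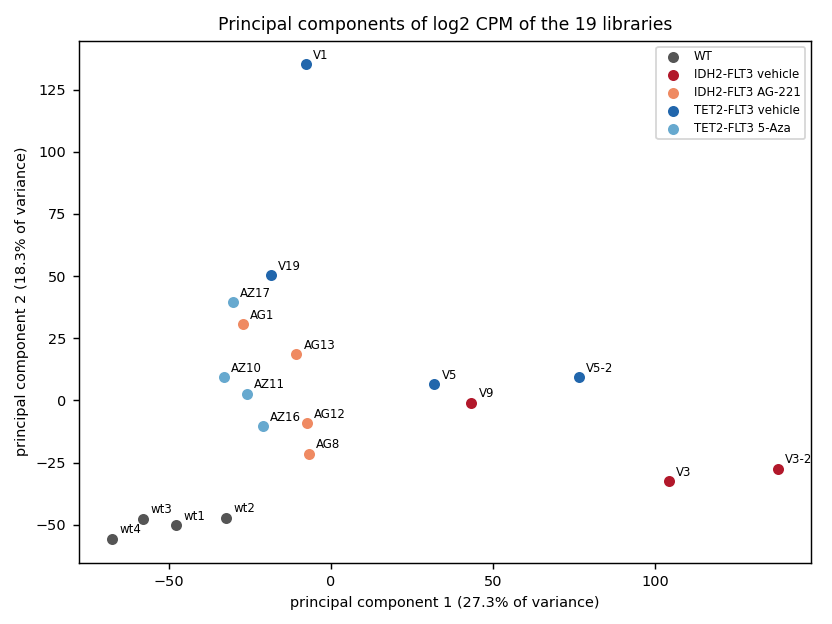
Positions of the 19 libraries on the first 2 principal components of log2 CPM, colored by group and labelled by library.

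Tet2, the deleted dioxygenase gene, gave 122, 117, 137 and 145 CPM in the 4 WT libraries and 188, 120.3 and 141 CPM in the 3 IDH2-FLT3 vehicle libraries. It gave 152, 116, 161 and 90.2 CPM with AG-221, 118, 156, 94.1 and 58.7 CPM in TET2-FLT3 vehicle and 88.9, 107, 59.6 and 36.5 CPM with 5-Aza. A count over the whole gene need not reveal a deletion of part of it, and the TET2-FLT3 vehicle level did not differ from WT by the test (log2 fold change -0.29 ± 0.31, adjusted p = 0.580). Tet2 also did not pass between IDH2-FLT3 vehicle and WT (0.20 ± 0.33, adjusted p = 0.699), between AG-221 and vehicle (-0.20 ± 0.33, adjusted p = 0.702) or between 5-Aza and vehicle (-0.55 ± 0.31, adjusted p = 0.496). Idh2, the enzyme that carries the engineered point mutation in 1 line, read 187, 203, 191 and 132 CPM in WT. Its levels were 153, 545 and 237 CPM in IDH2-FLT3 vehicle, 273, 204, 154 and 123 CPM with AG-221, 403, 274, 183 and 526 CPM in TET2-FLT3 vehicle and 307, 259, 229 and 360.2 CPM with 5-Aza. Idh2 did not pass in IDH2-FLT3 vehicle (0.81 ± 0.39, adjusted p = 0.143) or TET2-FLT3 vehicle against WT (0.96 ± 0.36, adjusted p = 0.0940), with AG-221 (-0.72 ± 0.39, adjusted p = 0.213) or with 5-Aza (-0.26 ± 0.36, adjusted p = 0.819). Flt3, the receptor kinase that carries the internal tandem duplication in both lines, fell in IDH2-FLT3 vehicle (155 ± 101 against 408 ± 110.2 CPM, log2 fold change -1.40 ± 0.46, adjusted p = 0.0356, †0.150). That call ended without wt3, wt4, V3 or V3-2 (adjusted p = 0.0909, 0.0899, 0.150 and 0.102). Flt3 did not pass in TET2-FLT3 vehicle (-0.07 ± 0.41, adjusted p = 0.927), with AG-221 (0.99 ± 0.45, adjusted p = 0.146) or with 5-Aza (-0.76 ± 0.41, adjusted p = 0.469).

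The first comparison asks how stem and progenitor cells of IDH2-FLT3 leukemia differed from WT cells, with 3 and 4 libraries. Stem cell genes fell in the leukemic cells. Hlf, a transcription factor of stem cells, went from 863 ± 212 to 32.2 ± 26.9 CPM (log2 fold change -4.75 ± 0.56, adjusted p = 3.60e-05), and the protein C receptor gene Procr from 64.9 ± 8.29 to 6.86 ± 5.89 CPM (-3.25 ± 0.42, adjusted p = 6.10e-05). Granulocyte and monocyte genes rose, with the myeloperoxidase gene Mpo at 37067 ± 25879 CPM against 2393 ± 1866 CPM (log2 fold change 3.95 ± 0.67, adjusted p = 5.57e-04). Csf1r, the macrophage growth factor receptor gene, stood at 355 ± 254 against 20.7 ± 9.599 CPM (4.10 ± 0.62, adjusted p = 2.49e-04). B-cell and erythroid genes were nearly lost. Cd79a, part of the B-cell receptor, dropped from 74.0 ± 10.7 to 0.375 ± 0.251 CPM (-7.66 ± 0.94, adjusted p = 4.78e-05), and Ermap, an erythroid membrane protein, from 48.0 ± 18.3 to 0.655 ± 0.628 CPM (-6.20 ± 0.87, adjusted p = 1.43e-04).

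In the stem cell list 12 of 22 fell, 1 rose and 9 did not pass (list alone 16 and 1). The signaling receptor Slamf1 was among those lost (-5.22 ± 0.93), and the list had a median of -2.16 (adjusted p = 5.93e-10, estimated 0.0720). Its scores against WT were -3.54 and -3.80 in V3 and V3-2, which the labels do not say are separate animals, and -1.15 in V9, so these 2 libraries carry most of the size. Of lymphoid-primed progenitor genes, 12 of 21 fell, 0 rose and 9 did not pass (list alone 14 and 0). Il7r, the interleukin-7 receptor gene, read 0.729 ± 0.695 against 43.6 ± 12.3 CPM (-5.93 ± 1.20), and these genes had a median of -2.03 (adjusted p = 1.02e-06, estimated 0.0720). In the granulocyte-monocyte progenitor list, which moved the other way, 18 of 23 rose, 0 fell and 5 did not pass (list alone 19 and 0). Its granule protease gene Ctsg rose from 415 ± 249 to 2646 ± 1439 CPM (log2 fold change 2.67 ± 0.45, adjusted p = 5.22e-04), and the list had a median of 2.33 (adjusted p = 4.79e-10, estimated 0.1254). Among monocyte genes 12 of 17 rose, 3 fell and 2 did not pass (list alone 13 and 4). The chemokine receptors Cx3cr1 (3.48 ± 0.43) and Ccr2 (3.31 ± 0.58) and the lysozyme gene Lyz2 (2.404 ± 0.51) rose, in a list with a median of 2.49 (adjusted p = 8.17e-05, estimated 0.185). Of mature neutrophil genes 8 of 19 rose, 0 fell and 11 did not pass (list alone 12 and 0), with a median of 1.79 (adjusted p = 0.00299, estimated 0.49997). Dendritic cell genes split, 7 up and 8 down of 21 (8 and 8 for the list alone). Their median of 1.07 and mean of -0.11 differed in sign (adjusted p = 0.660).

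Of erythroid genes 17 of 22 fell, 1 rose and 4 did not pass (list alone 19 and 1), with a median of -4.36 (adjusted p = 7.38e-13, estimated 0.0602). The erythroid and megakaryocytic transcription factor Gata1 fell from 38.1 ± 15.6 to 4.16 ± 1.69 CPM (log2 fold change -3.20 ± 0.58, adjusted p = 9.27e-04). Its partner Gata2 fell from 211 ± 11.99 to 60.7 ± 21.4 CPM (-1.80 ± 0.33) and the water channel gene Aqp1 from 36.7 ± 13.02 to 1.82 ± 0.592 CPM (-4.33 ± 0.62). Among B-cell genes 17 of 19 fell, 0 rose and 2 did not pass (list alone the same). Their median was -6.11, or -5.88 with the gene at 0 counts set to its bound (adjusted p = 3.34e-15, estimated 0.0305). Vpreb3, a pre-B-cell gene, stood at 0.336 ± 0.0908 against 67.7 ± 26.1 CPM (-7.58 ± 0.94). Of T and NK cell genes 10 of 19 fell, 0 rose and 9 did not pass (list alone 13 and 1), with a median of -3.31 (adjusted p = 1.02e-06, estimated 0.0910). In the megakaryocyte list 8 of 22 fell, 1 rose and 13 did not pass (list alone 8 and 2). The platelet chemokine Pf4 (-5.26 ± 0.94) and the platelet glycoprotein Gp9 (-2.58 ± 0.41) fell, and the list had a median of -0.98 (adjusted p = 0.00299, estimated 0.0678). Mast cell genes split with 4 up and 7 down of 19 (adjusted p = 0.392).

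Proliferation genes were higher. In the G2/M list 9 of 39 rose, 0 fell and 30 did not pass (list alone 11 and 0), with a median of 0.58 (adjusted p = 2.75e-05, estimated 0.190). The mitotic checkpoint kinase gene Bub1b stood at 229 ± 51.6 CPM against 90.2 ± 15.2 CPM (1.34 ± 0.30). In the S phase list 7 of 33 rose, 0 fell and 26 did not pass (list alone the same), with a median of 0.42 (adjusted p = 3.43e-04, estimated 0.144). Interferon-induced genes fell on balance, as 14 of 48 fell, 1 rose and 33 did not pass (list alone 15 and 1), with a median of -0.48 (adjusted p = 0.00450, estimated 0.452). Ifi44 and Ifit1, both induced by interferon, dropped from 83.1 ± 21.4 to 3.27 ± 3.12 CPM (-4.69 ± 0.55) and from 20.04 ± 5.39 to 1.79 ± 1.12 CPM (-3.51 ± 0.45). Ddx58, an RNA sensor, went from 85.4 ± 6.11 to 24.1 ± 2.07 CPM (-1.82 ± 0.27) and Ifi44l from 54.0 ± 28.5 to 0.129 ± 0.183 CPM (-8.77 ± 0.74). Of MHC class II genes 5 of 11 rose, 0 fell and 6 did not pass (list alone 6 and 0). H2-Ab1, a class II chain, rose (2.60 ± 0.78, †0.179), and the list had a median of 1.396 (adjusted p = 0.0270, estimated 0.565). In the unfolded protein list 9 of 25 rose, 1 fell and 15 did not pass (list alone 12 and 1). The chaperones Hyou1 (2.76 ± 0.55) and Hsp90b1 (1.43 ± 0.30) rose, with the list at a median of 1.03 (adjusted p = 8.52e-05, estimated 0.0810). Of hypoxia and glycolysis genes 8 of 28 rose, 2 fell and 18 did not pass (list alone 9 and 2). Gpi1, a glycolytic enzyme, rose (1.57 ± 0.33) and the hypoxia-induced Ndrg1 fell (-1.03 ± 0.25), in a list with a median of 0.55 (adjusted p = 0.0177, estimated 0.144).

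Hox cluster genes were lower, as 7 of 16 fell, 0 rose and 9 did not pass (list alone 8 and 0). Hoxa5 went from 38.3 ± 14.2 to 6.68 ± 3.92 CPM (-2.52 ± 0.56), and the list had a median of -1.88 (adjusted p = 9.67e-05, estimated 0.107). Of hematopoietic transcription factors 17 of 39 fell, 7 rose and 15 did not pass (list alone 19 and 7), with a median of -1.36 (adjusted p = 6.27e-04, estimated 0.104). In the MAPK feedback list 8 of 15 fell, 0 rose and 7 did not pass (list alone the same). The ERK phosphatase Dusp6 stood at 17.4 ± 6.18 against 87.4 ± 26.5 CPM (-2.33 ± 0.58), and the list had a median of -1.57 (adjusted p = 5.88e-04, estimated 0.144). Of imprinted genes 6 of 13 fell, 0 rose and 7 did not pass (list alone 9 and 0). Phlda2 lost nearly all its RNA (-6.38 ± 0.79), and the list had a median of -1.74 (adjusted p = 7.91e-06, estimated 0.0602). Single genes that rose included Id1, an inhibitor of helix-loop-helix factors (3.74 ± 0.42), and the cytokine feedback gene Socs2 (5.26 ± 0.98). The secreted protein gene Ccn3 (6.69 ± 0.80) and the integrin gene Itgae (6.28 ± 1.03‡) rose too.

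In all, 2428 genes passed an adjusted p of 0.05 in edgeR, 1195 higher and 1233 lower. After a correction for GC content and length 2354 were higher and 1182 lower, and from FPKM 560 and 2153, so the balance of directions depends on the scaling. Of tested genes 37.1% did not overlap between the groups, where chance gives 5.71%. The count was 1567 without wt3, 1477 without wt4, 1266 without V3 and 1488 without V3-2. The MHC class II call ended without V9 (adjusted p = 0.374) and the neutrophil call without V3 (adjusted p = 0.112).

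**Figure D2:**
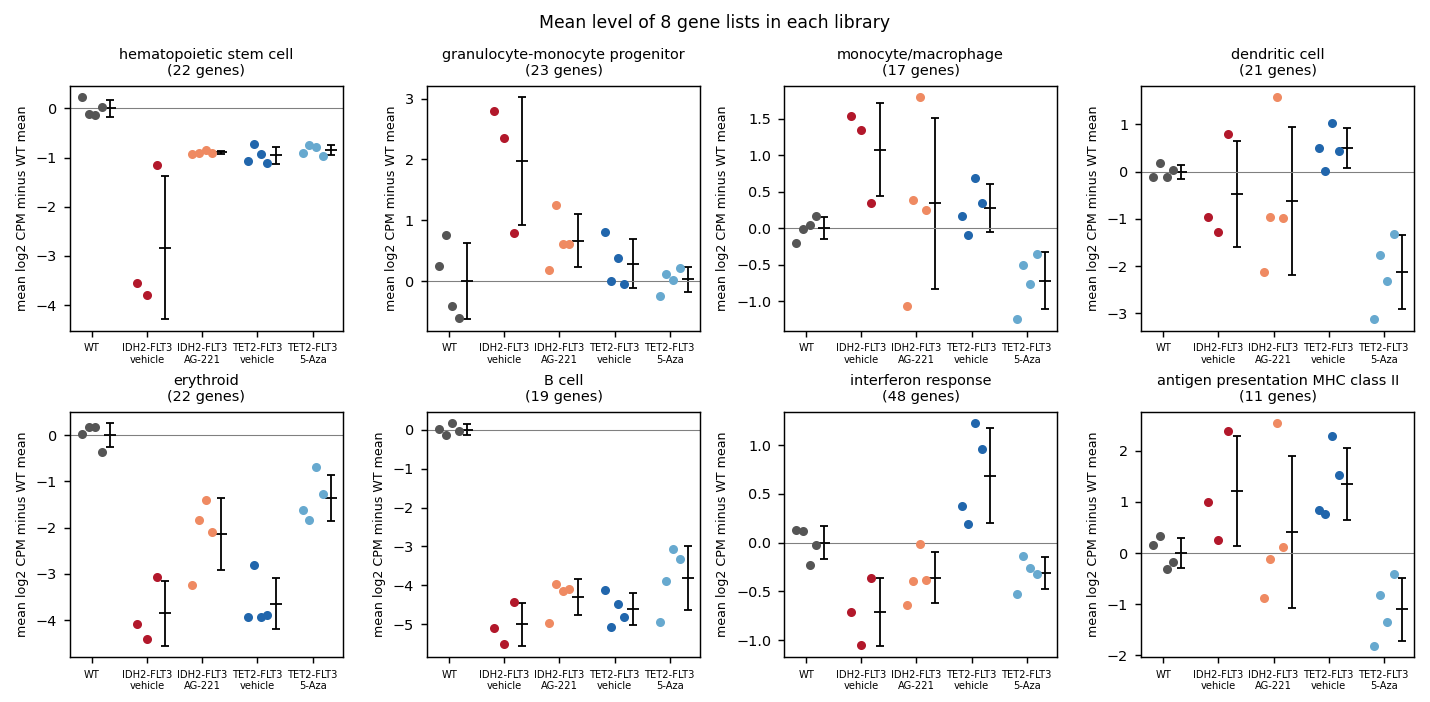
Mean log2 CPM of the genes of 8 fixed lists in each library, relative to the WT mean. Black marks give the group mean and SD.

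The second comparison asks how TET2-FLT3 leukemic cells differed from WT cells, with 4 libraries each. The losses of erythroid and B-cell RNA were again large. The erythroid claudin gene Cldn13 fell from 18.1 ± 2.73 to 0.154 ± 0.0944 CPM (log2 fold change -6.86 ± 0.65, adjusted p = 3.55e-06), Gata1 from 38.1 ± 15.6 to 1.79 ± 0.717 CPM (-4.37 ± 0.55, adjusted p = 9.01e-05), and Cd79a from 74.0 ± 10.7 to 0.287 ± 0.0890 CPM (-8.04 ± 0.85, adjusted p = 1.22e-05). Genes of cytokine signaling rose, among them the STAT5 targets Cish, from 29.0 ± 5.32 to 183 ± 55.6 CPM (2.66 ± 0.48, adjusted p = 0.00210), and Socs2, from 0.177 ± 0.179 to 13.1 ± 4.64 CPM (6.13 ± 0.98, adjusted p = 7.34e-04). Interferon-induced genes were higher rather than lower than in WT. Ifi204, a DNA sensor of the interferon response, stood at 23.4 ± 6.63 CPM against 2.08 ± 0.734 CPM (3.48 ± 0.53, adjusted p = 4.69e-04). Hlf fell from 863 ± 212 to 191 ± 95.6 CPM (-2.17 ± 0.44, adjusted p = 0.00439) and Slamf1 from 8.94 ± 2.31 to 0.952 ± 0.419 CPM (-3.25 ± 0.72, adjusted p = 0.00827).

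In the erythroid list 17 of 22 fell, 0 rose and 5 did not pass (list alone 18 and 1). Ermap fell too (-6.91 ± 0.80). The median was -4.25, or -4.23 with the gene at 0 counts set to its bound (adjusted p = 2.71e-16, estimated 0.0252). Of B-cell genes 16 of 19 fell, 0 rose and 3 did not pass (list alone the same). Vpreb3 (-7.71 ± 0.84) and the B-cell adaptor Blnk (-2.69 ± 0.52) were among them, and the list had a median of -4.98 (adjusted p = 1.82e-20, estimated 0.00838). Of megakaryocyte genes 9 of 22 fell, 0 rose and 13 did not pass (list alone the same). Gp9 read 7.65 ± 1.89 against 35.0 ± 1.76 CPM (-2.19 ± 0.36) and Pf4 14.1 ± 13.3 against 144 ± 18.96 CPM (-3.38 ± 0.75), in a list with a median of -0.62 (adjusted p = 6.27e-04, estimated 0.0252). In the imprinted list 6 of 13 fell, 0 rose and 7 did not pass (list alone 7 and 0). Peg12 stood at 5.54 ± 4.33 against 46.1 ± 4.74 CPM (-3.05 ± 0.76) and Phlda2 also fell (-2.57 ± 0.55), and the list had a median of -1.62 (adjusted p = 6.86e-07, estimated 0.0252). Among mast cell genes 8 of 19 fell, 2 rose and 9 did not pass (list alone the same). The monoamine transporter Slc18a2 was one that fell (-1.89 ± 0.32), and these genes had a median of -1.46 (adjusted p = 6.27e-04, estimated 0.141). Of hematopoietic transcription factors 9 of 39 fell, 2 rose and 28 did not pass (list alone 10 and 4). Gata2 dropped from 211 ± 11.99 to 65.9 ± 25.7 CPM (-1.68 ± 0.30), and the list had a median of -0.79 (adjusted p = 0.00265, estimated 0.141).

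In the stem cell list 5 of 22 fell, 2 rose and 15 did not pass (list alone the same). The orphan receptor Gprc5c rose in it (3.25 ± 0.79, †0.0508), while the list had a median of -0.98 (adjusted p = 0.00192, estimated 0.263). Of lymphoid-primed genes 6 of 21 fell, 0 rose and 15 did not pass (list alone 9 and 0), with a median of -0.94 (adjusted p = 1.65e-04, estimated 0.141). Among T and NK cell genes 5 of 19 fell, 1 rose and 13 did not pass (list alone 6 and 1). The surface glycoprotein Thy1 rose from 10.6 ± 3.17 to 147 ± 68.1 CPM (3.79 ± 0.61), while the list had a median of -1.34 (adjusted p = 0.00142, estimated 0.216). Monocyte genes split, as 6 of 17 rose, 4 fell and 7 did not pass (list alone 9 and 6). Ccr2 (2.86 ± 0.55) and the pore-forming Mpeg1 (3.41 ± 0.76) rose, in a list with a median of 1.27 (adjusted p = 0.0155, estimated 0.400). Granulocyte-monocyte genes moved less, as 3 of 23 rose, 0 fell and 20 did not pass (list alone 4 and 0). Ctsg stood at 1261 ± 471 against 415 ± 249 CPM (1.60 ± 0.41, †0.0731), and the list had a median of 0.39 (adjusted p = 0.0320, estimated 0.567). Dendritic cell genes had a median of 0.83 with 8 up and 2 down (adjusted p = 0.132), and neutrophil genes a median of -0.81 (adjusted p = 0.179998).

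Of interferon genes 11 of 48 rose, 0 fell and 37 did not pass (list alone 18 and 0). The chemokine Cxcl10 rose (2.71 ± 0.48) and Parp9 stood at 146 ± 39.9 against 63.6 ± 4.67 CPM (1.20 ± 0.22), and the list had a median of 0.81 (adjusted p = 4.39e-08, estimated 0.141). Interferon scores against WT were 1.22 and 0.96 in V5 and V5-2, which may be 1 animal, but 0.37 and 0.19 in V1 and V19 (WT -0.23 to 0.13), and with 2 of the 4 vehicle libraries at a time the median ran from 0.13 to 0.98. Of MHC class II genes 4 of 11 rose, 0 fell and 7 did not pass (list alone 6 and 0). H2-Ab1 (3.02 ± 0.76, †0.0608) and the lysosomal reductase Ifi30 (2.32 ± 0.51) rose, with the list at a median of 1.45 (adjusted p = 8.34e-04, estimated 0.322). In the MHC class I list 1 of 15 rose, 0 fell and 14 did not pass (list alone 2 and 0). Psmb9, an immunoproteasome subunit, was the gene that rose (0.87 ± 0.28, †0.130), a call that ended under 13 of 19 other settings, among them any WT library, V1 or V5 left out. The list had a median of 0.58 (adjusted p = 0.0444, estimated 0.253). Of STAT5 targets 8 of 25 rose, 0 fell and 17 did not pass (list alone 12 and 1). The kinase gene Pim1 rose (2.24 ± 0.51), in a list with a median of 0.85 (adjusted p = 6.15e-05, estimated 0.141). In the MAPK feedback list 5 of 15 fell, 1 rose and 9 did not pass (list alone 8 and 1). Dusp6 stood at 15.4 ± 4.45 against 87.4 ± 26.5 CPM (-2.51 ± 0.52‡), and the list had a median of -1.37 (adjusted p = 1.13e-04, estimated 0.141). Id1 rose from 4.23 ± 1.52 to 43.8 ± 11.1 CPM (3.37 ± 0.40), Ccn3 from 0.158 ± 0.1253 to 91.7 ± 28.4 CPM (9.10 ± 0.83) and Itgae from 0.511 ± 0.0641 to 63.8 ± 17.8 CPM (6.94 ± 1.03‡).

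Shifts upward were found in 6 further lists. In the S phase list 2 of 33 rose, 0 fell and 31 did not pass (list alone 1 and 0), with a median of 0.44 (adjusted p = 0.00631, estimated 0.253). In the G2/M list 2 of 39 rose, 1 fell and 36 did not pass (list alone 1 and 0). The mitotic activator Cdc20 rose (0.84 ± 0.22, †0.0697), and the list had a median of 0.42 (adjusted p = 0.00854, estimated 0.400). Of hypoxia genes 4 of 28 rose, 0 fell and 24 did not pass (list alone 6 and 0). The oxygen-sensing hydroxylase Egln3 rose (2.25 ± 0.45), and the list had a median of 0.44 (adjusted p = 0.00920, estimated 0.141). Among unfolded protein genes 3 of 25 rose, 0 fell and 22 did not pass (list alone 4 and 0). Pdia4, a disulfide isomerase, rose (1.27 ± 0.34, †0.0808), and the list had a median of 0.52 (adjusted p = 0.0105, estimated 0.216). Immediate-early and heat-shock genes split, as 3 of 26 rose, 1 fell and 22 did not pass (list alone 6 and 1). The early-response factor Egr1 fell (-2.87 ± 0.75, †0.0606) and the chaperone Hspa8 rose (1.65 ± 0.35), in a list with a median of 0.77 (adjusted p = 0.00766, estimated 0.216). Of respiratory chain genes 3 of 67 rose, 0 fell and 64 did not pass (list alone 2 and 0), with a median of 0.48 (adjusted p = 0.00766, estimated 0.567). This median was -0.05 from the FPKM values and 0.00 without V1 (adjusted p = 0.914).

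For this pair 1199 genes passed, 524 higher and 675 lower, and 18.5% did not overlap between the groups (chance 2.86%). After the GC and length correction 1589 were higher and 668 lower, and from FPKM 304 and 1580, so the balance depends on the scaling here too. Without wt1, wt3 and wt4 the count was 638, 563 and 503. The granulocyte-monocyte call ended without wt3, wt4, V1 or V5 (adjusted p = 0.108, 0.189, 0.301 and 0.0618). The MHC class I call ended without wt3, wt4, V5 or V5-2 (adjusted p = 0.0728, 0.0573, 0.167 and 0.112) and the G2/M call without V5 (adjusted p = 0.0656).

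Treatment with AG-221 was compared with vehicle in the IDH2-FLT3 line, with 4 and 3 libraries. Stem cell genes were higher in treated cells. Hlf rose from 32.2 ± 26.9 to 305 ± 129.5 CPM (log2 fold change 3.25 ± 0.52, adjusted p = 0.00277‡), Procr from 6.86 ± 5.89 to 35.5 ± 6.61 CPM (2.38 ± 0.40, adjusted p = 0.00338‡) and the homeobox gene Hoxb5 from 0.551 ± 0.186 to 7.68 ± 5.82 CPM (3.81 ± 0.67, adjusted p = 0.00400‡). Granulocyte and monocyte genes were lower, with Mpo at 3754 ± 1787 CPM against 37067 ± 25879 CPM (-3.30 ± 0.65, adjusted p = 0.00867, †0.0563), Csf1r at 18.3 ± 1.97 against 355 ± 254 CPM (-4.27 ± 0.63, adjusted p = 0.00267‡) and Cx3cr1 at 8.98 ± 3.89 against 75.9 ± 41.7 CPM (-3.08 ± 0.42, adjusted p = 0.00264‡). The erythroid gene Hemgn rose from 6.15 ± 6.57 to 50.1 ± 6.61 CPM (3.04 ± 0.57, adjusted p = 0.00626‡) and Gata2 from 60.7 ± 21.4 to 131 ± 29.9 CPM (1.10 ± 0.32, adjusted p = 0.0383, †0.126). Gata1 (0.72 ± 0.53, adjusted p = 0.364), Id1 (-0.03 ± 0.39, adjusted p = 0.969) and Socs2 (-1.60 ± 0.80, adjusted p = 0.186) did not pass.

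In the stem cell list 7 of 22 rose, 0 fell and 15 did not pass (list alone 11 and 0). Slamf1 read 2.80 ± 2.57 against 0.235 ± 0.292 CPM (3.56 ± 0.88, †0.109), and the list had a median of 1.61 (adjusted p = 3.33e-07, estimated 0.298). The median was 1.04 without V3-2 and V5-2, and the scores of -0.92 to -0.85 with AG-221 lay near that of V9, so the rise rests mostly on V3 and V3-2. Of granulocyte-monocyte progenitor genes 8 of 23 fell, 0 rose and 15 did not pass (list alone 17 and 0). Prtn3, a granule protease, stood at 1405 ± 408 against 4745 ± 2071 CPM (-1.76 ± 0.40, †0.0776), and the list had a median of -1.56 (adjusted p = 1.98e-05, estimated 0.385). Of monocyte genes 7 of 17 fell, 3 rose and 7 did not pass (list alone 10 and 4). The macrophage receptor Adgre1 (-2.66 ± 0.56, †0.0706) and the lipopolysaccharide receptor Cd14 (-3.69 ± 0.80, †0.0718) fell, in a list with a median of -1.52 (adjusted p = 6.00e-04, estimated 0.385). Among lymphoid-primed genes 2 of 21 rose, 1 fell and 18 did not pass (list alone 3 and 2). The adaptor Tespa1 rose (1.80 ± 0.35, †0.0581), and the list had a median of 0.77 (adjusted p = 0.0170, estimated 0.385). In the erythroid list 9 of 22 rose, 1 fell and 12 did not pass (list alone 14 and 1). Cldn13 rose (3.68 ± 0.66‡) and the blood group gene Rhd stood at 4.58 ± 1.99 against 0.693 ± 0.226 CPM (2.74 ± 0.74, †0.140), and the list had a median of 2.36 (adjusted p = 4.50e-05, estimated 0.385). Of T and NK cell genes 9 of 19 rose, 0 fell and 10 did not pass (list alone 11 and 0). The T-cell receptor chain Cd3d was among them (3.53 ± 0.92, †0.127), and the list had a median of 2.16 (adjusted p = 3.79e-06, estimated 0.298).

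Of Hox cluster genes 4 of 16 rose, 0 fell and 12 did not pass (list alone 5 and 0), Hoxa5 among them (2.21 ± 0.56, †0.106), with a median of 1.42 (adjusted p = 0.00154, estimated 0.385). Of interferon genes 8 of 48 rose, 0 fell and 40 did not pass (list alone 9 and 0), with a median of 0.27 (adjusted p = 0.0406, estimated 0.601). The antiviral Rsad2 went from 4.71 ± 3.12 to 21.8 ± 6.46 CPM (2.22 ± 0.45, †0.0671), the GTPase Gbp2 from 24.9 ± 2.99 to 54.3 ± 11.98 CPM (1.12 ± 0.24, †0.0617) and Ifit1 from 1.79 ± 1.12 to 6.41 ± 0.840 CPM (1.87 ± 0.42, †0.0849). Of imprinted genes 2 of 13 rose, 0 fell and 11 did not pass (list alone 3 and 0), Ppp1r9a among them (1.87 ± 0.42, †0.0893), with a median of 0.77 (adjusted p = 0.0201, estimated 0.385). In the unfolded protein list 5 of 25 fell, 0 rose and 20 did not pass (list alone 7 and 1). Hyou1 stood at 60.8 ± 13.2 against 328 ± 309 CPM (-2.43 ± 0.54, †0.160) and the degradation factor Edem1 fell (-1.46 ± 0.34, †0.145), and the list had a median of -0.88 (adjusted p = 6.00e-04, estimated 0.298). In the G2/M list 1 of 39 fell, 0 rose and 38 did not pass (list alone 0 and 0). Bub1b was the gene that fell (-0.95 ± 0.30, †0.201), and the list had a median of -0.30 (adjusted p = 0.0307, estimated 0.557). Of S phase genes 0 of 33 members passed by either adjustment. The replication helicase Mcm2 read -0.90 ± 0.29, adjusted p = 0.0553, and the list had a median of -0.29 (adjusted p = 0.0307, estimated 0.455). Of ribosomal protein genes 2 of 77 rose, 0 fell and 75 did not pass (list alone 0 and 0). Rpl22l1 (1.38 ± 0.41, †0.181) and Rpl36 (1.21 ± 0.38, †0.218) rose, in a list with a median of 0.73 (adjusted p = 2.96e-06, estimated 0.436). The respiratory chain list had a median of 0.60 (adjusted p = 0.00287, estimated 0.601), while of 67 members 2 fell (0 for the list alone) and 0 rose. Atp5b of ATP synthase was among those that fell (-1.07 ± 0.29, †0.0932), and Uqcrh of complex III did not pass (1.28 ± 0.44, adjusted p = 0.0651).

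Large single changes included the glycine decarboxylase Gldc, up from 0.880 ± 1.2531 to 39.7 ± 8.95 CPM (5.53 ± 0.94‡), and the retinaldehyde dehydrogenase Aldh1a1, up from 0.805 ± 0.851 to 15.5 ± 8.47 CPM (4.33 ± 0.78‡). The membrane protein gene Tmem178 went down from 40.8 ± 42.4 to 0.478 ± 0.470 CPM (-6.43 ± 1.13‡), and the integrin gene Itga1 from 49.7 ± 39.3 to 2.08 ± 0.653 CPM (-4.58 ± 0.72‡). Lists that did not pass included neutrophil genes (median 0.05, adjusted p = 0.869), MHC class II genes (median -0.36, adjusted p = 0.127) and DNA methylation machinery (median -0.16, adjusted p = 0.869).

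Here 1145 genes passed, 519 higher and 626 lower, and 23.8% did not overlap between the groups (chance 5.71%). From FPKM 924 were higher and 312 lower. With edgeR fitted to these 7 libraries alone 0 genes passed, while 2768 had an unadjusted p under 0.05. DESeq2 and limma-voom called 2108 and 1832. The count was 97 without V3, 110 without V3-2 and 2252 without V9. Without AG1, AG12, AG13 and AG8 it was 600, 572, 658 and 748. The labels do not say that V3 and V3-2 are separate animals, and the count was 197 with V3 and V3-2 (and V5 and V5-2) summed and 265 without V3-2 and V5-2, both chosen after the data were seen. Without V3-2 the list calls ended for lymphoid-primed genes (adjusted p = 0.0938), respiratory chain genes (adjusted p = 0.146), interferon genes (adjusted p = 0.146) and imprinted genes (adjusted p = 0.104). The interferon call also ended without AG13 or AG8 (adjusted p = 0.147 and 0.0547), and the imprinted call without V3 or V9 (adjusted p = 0.297 and 0.274). The G2/M and S phase calls ended without V3 (adjusted p = 0.297 and 0.113), V9 (adjusted p = 0.0721 and 0.0766) or AG13 (adjusted p = 0.162 and 0.149).

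**Figure D3:**
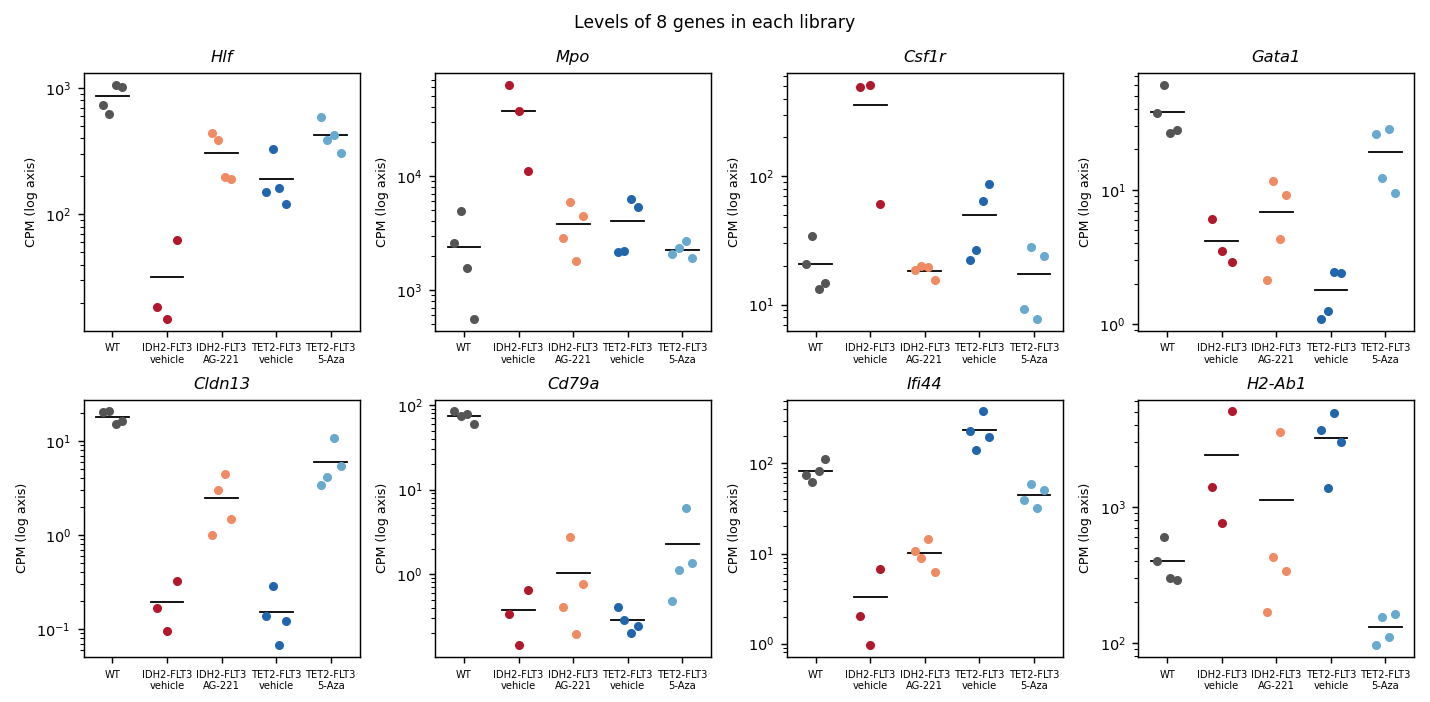
Levels of 8 genes in each of the 19 libraries on a log axis, with group means as black lines.

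The 5-Aza comparison in the TET2-FLT3 line had 4 libraries on each side. Genes of antigen-presenting dendritic cells fell with the drug. The chemokine receptor Xcr1 went from 178 ± 73.2 to 2.22 ± 1.04 CPM (log2 fold change -6.32 ± 0.97, adjusted p = 0.00229), the class II chains H2-Ab1 from 3221 ± 1466 to 131 ± 32.9 CPM (-4.62 ± 0.82, adjusted p = 0.00525) and H2-Eb1 from 1999 ± 796 to 53.9 ± 29.7 CPM (-5.21 ± 0.92, adjusted p = 0.00521), and Itgae from 63.8 ± 17.8 to 0.395 ± 0.168 CPM (-7.32 ± 1.06, adjusted p = 0.00199‡). Erythroid genes rose, with Cldn13 at 5.91 ± 3.30 CPM against 0.154 ± 0.0944 CPM (5.25 ± 0.62, adjusted p = 4.98e-04) and Ermap at 11.8 ± 3.08 against 0.396 ± 0.323 CPM (4.89 ± 0.75, adjusted p = 0.00229‡). The transcription factors Gata1 and Gata2 stood at 19.1 ± 9.56 against 1.79 ± 0.717 CPM (3.37 ± 0.53, adjusted p = 0.00243‡) and 174 ± 64.1 against 65.9 ± 25.7 CPM (1.4002 ± 0.30, adjusted p = 0.0162, †0.0910). Interferon-induced genes fell, among them Ifi204 at 2.06 ± 1.60 against 23.4 ± 6.63 CPM (-3.50 ± 0.53, adjusted p = 0.00229) and Ifi44 at 45.2 ± 11.9 against 236 ± 103 CPM (-2.38 ± 0.43, adjusted p = 0.00575).

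In the interferon list 10 of 48 fell, 0 rose and 38 did not pass (list alone 22 and 0), with a median of -0.86 (adjusted p = 1.27e-19, estimated 0.0602). The RNA helicase Dhx58 read 23.9 ± 3.92 against 70.9 ± 25.9 CPM (-1.57 ± 0.26) and the growth regulator Slfn1 0.951 ± 0.721 against 12.7 ± 7.18 CPM (-3.71 ± 0.66). Of dendritic cell genes 8 of 21 fell, 0 rose and 13 did not pass (list alone 13 and 1). The transcription factor Irf4 was among them (-2.59 ± 0.47), and the list had a median of -3.53 (adjusted p = 2.30e-12, estimated 0.167). Of MHC class II genes 5 of 11 fell, 0 rose and 6 did not pass (list alone 8 and 0). H2-Aa (-4.76 ± 0.92, †0.0577) and the invariant chain Cd74 (-5.09 ± 1.13, †0.0887) fell, in a list with a median of -2.01 (adjusted p = 3.41e-11, estimated 0.167). Of monocyte genes 2 of 17 fell, 0 rose and 15 did not pass (list alone 7 and 0). Mpeg1 stood at 27.0 ± 17.0 against 708 ± 499 CPM (-4.71 ± 0.81) and Ccr2 fell (-2.81 ± 0.55, †0.0634), and the list had a median of -1.28 (adjusted p = 7.95e-06, estimated 0.175). Of STAT5 targets 2 of 25 fell, 0 rose and 23 did not pass (list alone the same). The repressor Bcl6 fell (-2.65 ± 0.57, †0.0645) and Socs2 did not pass (-1.82 ± 0.76, adjusted p = 0.312), in a list with a median of -0.51 (adjusted p = 4.48e-04, estimated 0.175). Of immediate-early genes 2 of 26 fell, 0 rose and 24 did not pass (list alone the same). They were the stress factor Atf3 (-5.32 ± 1.19, †0.0943) and the transcription factor Klf2 (-3.34 ± 0.77, †0.110), and the list had a median of -0.71 (adjusted p = 0.00137, estimated 0.175).

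In the erythroid list 10 of 22 rose, 0 fell and 12 did not pass (list alone 13 and 0). Rhd read 8.53 ± 2.93 against 1.09 ± 1.399 CPM (3.02 ± 0.66, †0.0771). The list median was 2.86, or 2.26 with the gene at 0 counts set to its bound (adjusted p = 8.75e-15, estimated 0.0602). In the MAPK feedback list 3 of 15 rose, 0 fell and 12 did not pass (list alone 5 and 0), with a median of 0.93 (adjusted p = 3.85e-04, estimated 0.175). The ETS factor Etv5 stood at 15.7 ± 10.7 against 1.55 ± 0.636 CPM (3.31 ± 0.68, †0.0646), and the phosphatases Dusp6 (2.18 ± 0.52, †0.150) and Dusp4 (3.54 ± 0.89, †0.164) rose, calls that ended under 13 of 19 and 12 of 17 other settings, among them any vehicle library, AZ10 or AZ16 left out. In the megakaryocyte list 3 of 22 rose, 1 fell and 18 did not pass (list alone 7 and 1). Gp9 rose (1.69 ± 0.36, †0.0738) and the platelet protein Plek fell (-1.16 ± 0.27, †0.109), and the list had a median of 0.57 (adjusted p = 0.0286, estimated 0.167). Among mast cell genes 2 of 19 rose, 1 fell and 16 did not pass (list alone 4 and 1). The IgE receptor chain Fcer1a rose (2.94 ± 0.69, †0.115), in a list with a median of 0.67 (adjusted p = 0.0217, estimated 0.316). Of B-cell genes 1 of 19 rose, 0 fell and 18 did not pass (list alone 6 and 2). Cd79a was the gene that rose (3.02 ± 0.77, †0.328), with 6.07 CPM in AZ16 and 0.486 to 1.35 in the others. Its call ended under 14 of 18 other settings, among them leaving out any of the 8 libraries but AZ10 (1.83, adjusted p = 0.328 without AZ16). The list had a median of 0.77 (adjusted p = 0.0346, estimated 0.540). Slamf1 rose from 0.952 ± 0.419 to 9.79 ± 4.64 CPM (3.38 ± 0.72, †0.0706) in a stem cell list that did not pass (median 0.08, adjusted p = 0.253).

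Lists called with no called member were germline, imprinted, G2/M and unfolded protein genes. Germline genes had a median of 0.49 (adjusted p = 0.0307, estimated 0.175), with 1 risen over the list alone, and imprinted genes a median of 0.31 (adjusted p = 0.0446, estimated 0.319). G2/M genes had a median of 0.12 (adjusted p = 0.0162, estimated 0.541) and unfolded protein genes a median of -0.56 (adjusted p = 0.0286, estimated 0.316). Xlr4a (1.15 ± 0.33, adjusted p = 0.0840), Kcnq1ot1 (1.31 ± 0.66, adjusted p = 0.424), the kinetochore gene Cenpf (0.88 ± 0.31, adjusted p = 0.216) and the stress-secreted factor Manf (-0.91 ± 0.34, adjusted p = 0.249) did not pass. Of NF-kB targets 1 of 18 fell, 0 rose and 17 did not pass (list alone the same), with a median of -0.26 (adjusted p = 0.0286, estimated 0.167). The chemokine Ccl3 fell (-3.08 ± 0.58), and the apoptosis inhibitor Birc3 did not pass (-0.68 ± 0.24, adjusted p = 0.194). The receptor gene Tlr11 went down from 78.3 ± 50.5 to 0.451 ± 0.298 CPM (-7.41 ± 1.01), the transporter-family gene Slc16a11 went up from 0.575 ± 0.663 to 28.2 ± 18.4 CPM (5.61 ± 0.84‡), and Id1 did not pass (-0.51 ± 0.36, adjusted p = 0.613). DNA methylation machinery had a median of -0.08 (adjusted p = 0.686), and p53 targets had -0.07 (adjusted p = 0.477).

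With 5-Aza 222 genes passed, 51 higher and 171 lower, and 7.09% did not overlap between the groups (chance 2.86%). The count was 135 without V5 and 81, 143, 57 and 133 without AZ10, AZ11, AZ16 and AZ17. Without V5 the list calls ended for B-cell (adjusted p = 0.0749), germline (0.0770), imprinted (0.132), mast cell (0.0749), megakaryocyte (0.0921), NF-kB (0.0749) and unfolded protein genes (0.0749). Without V5-2 they ended for B-cell (0.0921), germline (0.204), imprinted (0.1804), mast cell (0.1804), NF-kB (0.0595) and G2/M genes (0.0921). Without V19 the B-cell (0.187) and megakaryocyte calls (0.0522) ended, and without V1 that of unfolded protein genes (0.163). Others ended without AZ10 (imprinted genes, 0.0646), AZ11 (germline and imprinted genes, 0.0617 and 0.155), AZ16 (B-cell and G2/M genes, 0.135 and 0.0922) and AZ17 (B-cell and NF-kB genes, 0.154 and 0.0714).

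What still differed from WT after treatment was asked next. With AG-221 the B-cell genes stayed low, Vpreb3 at 0.165 ± 0.238 CPM against 67.7 ± 26.1 CPM (log2 fold change -8.52 ± 0.89, adjusted p = 1.31e-05) and Cd79a at 1.04 ± 1.19 against 74.0 ± 10.7 CPM (-6.12 ± 0.75, adjusted p = 7.99e-05). Blnk stood at 1.57 ± 0.672 against 34.2 ± 7.15 CPM (-4.43 ± 0.57, adjusted p = 1.10e-04), the recombinase Rag2 at 1.12 ± 0.683 against 13.1 ± 4.56 CPM (-3.53 ± 0.58, adjusted p = 0.00141) and Gata1 at 6.82 ± 4.39 against 38.1 ± 15.6 CPM (-2.48 ± 0.50, adjusted p = 0.00710). Id1 (3.71 ± 0.41), Cish (3.18 ± 0.49), Socs2 (3.66 ± 0.94, †0.134), the kinase Pim2 (1.97 ± 0.53, †0.156), the histone-modifying Padi4 (1.05 ± 0.21), Ccn3 (8.22 ± 0.81), Gldc (8.81 ± 1.03) and Itgae (6.41 ± 1.01‡) were higher than in WT. Itgae read 153 CPM in AG13 and had a log2 fold change of 3.95 without it, and DESeq2 gave it no adjusted p. Hlf (305 ± 129.5 against 863 ± 212 CPM, -1.50 ± 0.43, adjusted p = 0.0679) and Gata2 (-0.69 ± 0.29, adjusted p = 0.285) did not pass. Among B-cell genes 14 of 19 fell, 0 rose and 5 did not pass (list alone 16 and 0), with a median of -4.41 (adjusted p = 2.73e-34, estimated 6.50e-04). In the erythroid list 8 of 22 fell, 0 rose and 14 did not pass (list alone 15 and 0). Ermap (-3.58 ± 0.66) and Cldn13 (-2.85 ± 0.50) were lower, and the list had a median of -2.10 (adjusted p = 8.57e-16, estimated 0.0273). Of megakaryocyte genes 2 of 22 fell, 0 rose and 20 did not pass (list alone 3 and 1). The caveolar protein Cavin2 stood at 1.95 ± 1.54 against 29.4 ± 8.72 CPM (-3.89 ± 0.77), and the list had a median of -0.86 (adjusted p = 1.45e-04, estimated 0.0270). In the stem cell list 2 of 22 fell, 0 rose and 20 did not pass (list alone 3 and 1), with a median of -0.70 (adjusted p = 1.75e-04, estimated 0.280). Of neutrophil genes 2 of 19 rose, 0 fell and 17 did not pass (list alone 10 and 0), with a median of 1.66 (adjusted p = 4.57e-07, estimated 0.280) and scores against WT from -0.28 in AG1 to 2.63 in AG12. Of granulocyte-monocyte genes 0 of 23 members passed by either adjustment, with a median of 0.68 (adjusted p = 3.84e-06, estimated 0.303). In the MAPK feedback list 2 of 15 fell, 0 rose and 13 did not pass (list alone 8 and 0), Etv5 among them (-2.81 ± 0.66, †0.0780), with a median of -1.22 (adjusted p = 4.27e-06, estimated 0.0819). Ifi44 (-3.05 ± 0.45), Ifit1 (-1.64 ± 0.37, †0.0617) and Ifi44l (-8.55 ± 0.65) stayed below WT, and the interferon list had a median of -0.29 (adjusted p = 0.0364, estimated 0.517). That call ended without wt1, wt2, AG1 or AG12 (adjusted p = 0.0860, 0.0986, 0.175 and 0.0688). For AG-221 against WT 321 genes passed, 123 higher and 198 lower (15.8% without overlap, chance 2.86%), and 190, 170 and 179 without wt1, wt3 and wt4.

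Cells treated with 5-Aza also kept low B-cell genes against WT. Cd79a read 2.26 ± 2.57 CPM against 74.0 ± 10.7 CPM (log2 fold change -5.02 ± 0.70, adjusted p = 5.86e-04), Vpreb3 1.96 ± 1.59 against 67.7 ± 26.1 CPM (-5.10 ± 0.72, adjusted p = 5.86e-04) and Il7r 1.39 ± 0.944 against 43.6 ± 12.3 CPM (-4.96 ± 0.9999, adjusted p = 0.0122, †0.0603). Gata1 (19.1 ± 9.56 against 38.1 ± 15.6 CPM, -0.9996 ± 0.47, adjusted p = 0.304) and Gata2 (174 ± 64.1 against 211 ± 11.99 CPM, -0.28 ± 0.29, adjusted p = 0.659) did not pass, while the erythroid Aqp1 was lower (-2.05 ± 0.49, adjusted p = 0.0342, †0.135). Siglech (-5.25 ± 1.29, †0.128), Ly6d (-4.35 ± 0.93, †0.0706), the transcription factor Spib (-4.55 ± 0.84) and Irf4 (-2.56 ± 0.47) were lower. The calls of Siglech, and of Cks2, Cdc20 and Pgk1 below, ended without any 1 of the 8 libraries, and that of Ly6d without wt1, AZ10, AZ11 or AZ17. Id1 (2.86 ± 0.40), Socs2 (4.31 ± 0.94, †0.0800), Pim2 (2.24 ± 0.53, †0.122), Thy1 (3.37 ± 0.60), Ccn3 (7.34 ± 0.79) and the lectin gene Clec2f (4.02 ± 0.65) were higher, and Ccl3 was lower (-3.45 ± 0.59). In the B-cell list 12 of 19 fell, 0 rose and 7 did not pass (list alone 15 and 0), with a median of -4.05 (adjusted p = 1.18e-26, estimated 0.00234). Of dendritic cell genes 4 of 21 fell, 0 rose and 17 did not pass (list alone 7 and 0), with a median of -1.68 (adjusted p = 1.49e-07, estimated 0.242). Of erythroid genes 1 of 22 fell, 0 rose and 21 did not pass (list alone 8 and 0), with a median of -1.38 (adjusted p = 3.57e-08, estimated 0.136). In the G2/M list 2 of 39 rose, 0 fell and 37 did not pass (list alone 3 and 0). Cks2 (1.10 ± 0.28, †0.193) and Cdc20 (0.86 ± 0.22, †0.208) rose, and the list had a median of 0.50 (adjusted p = 2.66e-08, estimated 0.136). The hypoxia list had a median of 0.28 (adjusted p = 0.0205, estimated 0.219), with the glycolytic kinase Pgk1 higher (0.93 ± 0.24, †0.172), and the list call ended without wt4 (adjusted p = 0.0520). For 5-Aza against WT 203 genes passed, 73 higher and 130 lower (25.0% without overlap, chance 2.86%). The count was 84, 81 and 83 without wt1, wt3 and wt4 and 100, 87, 93 and 73 without AZ10, AZ11, AZ16 and AZ17.

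The 2 leukemia lines were compared directly in their vehicle arms, with 3 and 4 libraries. Interferon-induced genes were lower in IDH2-FLT3 than in TET2-FLT3 cells. Ifi44l read 0.129 ± 0.183 CPM against 148 ± 28.3 CPM (log2 fold change -10.22 ± 0.76, adjusted p = 1.60e-07), Ifi44 3.27 ± 3.12 against 236 ± 103 CPM (-6.19 ± 0.59, adjusted p = 3.52e-06) and Ifit1 1.79 ± 1.12 against 38.0 ± 14.5 CPM (-4.43 ± 0.47, adjusted p = 1.26e-05). The ubiquitin-like Isg15 read 6.14 ± 3.72 against 52.2 ± 18.7 CPM (-3.09 ± 0.41, adjusted p = 2.95e-04‡) and Rsad2 4.71 ± 3.12 against 36.8 ± 9.11 CPM (-2.97 ± 0.46, adjusted p = 0.00152‡). Mpo (3.21 ± 0.65, †0.0678), the elastase Elane (3.54 ± 0.69, †0.0773), lactoferrin Ltf (4.95 ± 0.95‡), the neutrophil receptor Cd177 (4.96 ± 0.92‡) and Csf1r (2.82 ± 0.59, †0.0653) were higher in IDH2-FLT3 cells. The eosinophil genes Prg2 (6.52 ± 0.996‡) and Epx (6.27 ± 1.19‡) and the basophil and mast cell genes Prss34 (6.41 ± 1.03‡), Hdc (4.69 ± 0.68) and Fcer1a (3.98 ± 0.74, †0.0528) were higher too. Hlf (-2.57 ± 0.50, †0.0582), Procr (-2.64 ± 0.40‡), Hoxb6 (-5.20 ± 1.06, †0.0589), Thy1 (-2.44 ± 0.64, †0.173), Pim2 (-2.21 ± 0.59, †0.186), the cytokine feedback gene Socs3 (-2.67 ± 0.65, †0.128) and the X-linked Xlr4a (-4.47 ± 0.44) were lower. Flt3 (-1.32 ± 0.46, adjusted p = 0.1005) and Gata1 (1.17 ± 0.53, adjusted p = 0.213) did not pass. Of interferon genes 18 of 48 fell, 0 rose and 30 did not pass (list alone 31 and 0), with a median of -1.07 (adjusted p = 1.47e-18, estimated 0.142). Of granulocyte-monocyte genes 11 of 23 rose, 0 fell and 12 did not pass (list alone 17 and 0), with a median of 1.89 (adjusted p = 1.18e-09, estimated 0.322). Of neutrophil genes 9 of 19 rose, 0 fell and 10 did not pass (list alone 14 and 0), with a median of 2.60 (adjusted p = 1.13e-06, estimated 0.418). In the stem cell list 4 of 22 fell, 0 rose and 18 did not pass (list alone 8 and 0), with a median of -1.34 (adjusted p = 1.41e-09, estimated 0.240). The scores in TET2-FLT3 vehicle, -1.10 to -0.72, lay near that of V9, so this difference too rests mostly on V3 and V3-2. Of mast cell genes 3 of 19 rose, 1 fell and 15 did not pass (list alone 5 and 2), with a median of 0.64 (adjusted p = 0.0304, estimated 0.501). The mast cell call ended without V3, V3-2, V5 or V5-2 (adjusted p = 0.154, 0.0687, 0.0961 and 0.320). Between the lines 506 genes passed, 228 higher and 278 lower (8.59% without overlap, chance 5.71%), and 17 in a fit of these 7 libraries alone. The count was 114, 165 and 1293 without V3, V3-2 and V9, and 298, 825 and 1656 without V19, V5 and V5-2.

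**Figure D4:**
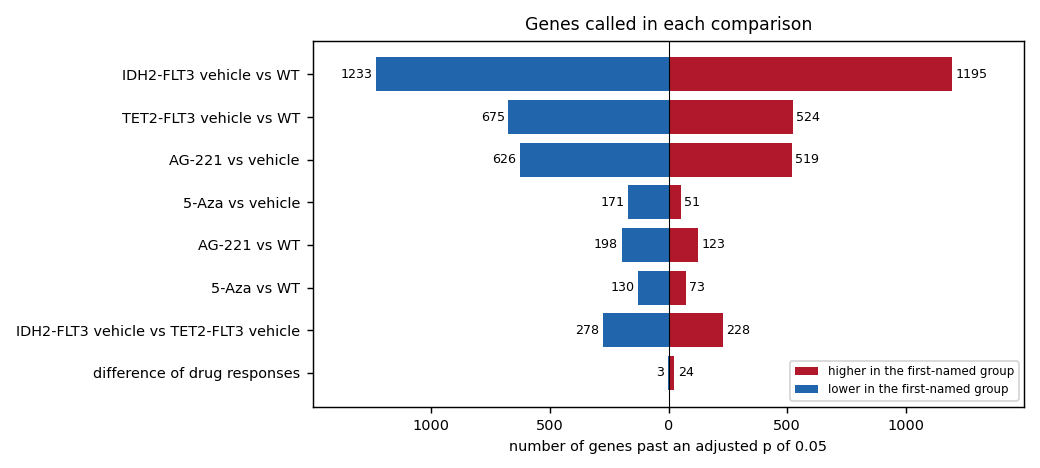
Number of genes past an adjusted p of 0.05 in each comparison, by direction, from 2428 in IDH2-FLT3 vehicle against WT to 27 in the last bar pair, the response to AG-221 minus the response to 5-Aza.

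The overlap of the leukemia signatures was examined with the shared WT group in mind. Both leukemia lines shared 743 calls of the same direction against WT, or 409, 352 and 324 without wt1, wt3 and wt4. Of the 743 307 were higher, such as Id1, Ccn3 and Itgae, and 436 lower, such as Cd79a, Ermap and Gata1, while 10 genes were called in opposite directions. Lists of these sizes drawn independently would share 52.9 and 70.4. In 20 simulations of unchanged leukemia groups measured against a common WT group, 0 calls were shared. That was nearly fixed in advance, as data without an effect give few calls. Among as many top genes 455 were shared on average (range 436 to 481). The covariance of the log2 fold changes was 1.36 against 0.149 simulated, and their correlation 0.693 against 0.456. With WT split so that each line had its own 2 WT libraries, 191 calls were shared on average (range 151 to 263), where independent lists gave 15.7. The covariance was then 1.48 and the correlation 0.627.

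Signs of the drug responses were set against those of the leukemia signatures. Of the IDH2-FLT3 calls, 96.3% had the opposite sign under AG-221, such as Hlf, Mpo and Csf1r. Simulated data without a drug effect gave 65.1%, because both comparisons use the vehicle libraries. Of the TET2-FLT3 calls, 91.9% were opposite under 5-Aza, such as Gata1 and H2-Ab1, against 65.9% simulated. With the vehicle libraries of that line split 2 and 2, so that none served both comparisons, the share was 71.0% on average (range 50.2 to 88.0). Across lines, which share no libraries, 76.5% of TET2-FLT3 calls were opposite under AG-221 (51.5% simulated). Of IDH2-FLT3 calls 76.3% were opposite under 5-Aza (50.4% simulated). Yet log2 CPM of V3-2 correlated more with V5-2 of the other line (0.882) than with V3 (0.851). V5-2 gave 0.835 with V5, V9 0.970 with V5 and 0.910 with V3. A trait common to vehicle libraries could give opposite signs within and across lines, and no simulation holds one. As gene sets, genes lower in TET2-FLT3 had a median log2 fold change of 1.02 under AG-221 and genes higher in it -0.39 (camera p = 0.0189 and 0.0893 with an estimated correlation). Genes higher in IDH2-FLT3 had a median of -0.41 under 5-Aza and genes lower in it 0.34 (camera p = 0.0412 and 0.0772 with an estimated correlation). Redone without V3-2 and V5-2, after the data were seen, these 4 medians were 0.71, -0.07, -0.37 and 0.24 (camera p = 0.0431, 0.696, 0.0922 and 0.144 with an estimated correlation).

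The response to AG-221 minus that to 5-Aza, tested by gene, cannot separate drug from line. Some interferon genes differed. Ifit1 rose with AG-221 by 1.87 and gave -1.66 with 5-Aza (difference 3.52 ± 0.56, adjusted p = 0.0140, †0.0542), and Ifi44 1.64 and -2.38 (difference 4.02 ± 0.66, adjusted p = 0.0140, †0.0695). Ccl3 gave 2.02 and -3.08 (difference 5.11 ± 0.85, adjusted p = 0.0140, †0.0695), and the lactate dehydrogenase Ldhd 3.48 and -0.77 (difference 4.25 ± 0.70, adjusted p = 0.0140, †0.0695). The cerebellar antigen gene Cdr2 gave -5.26 and 0.89 (difference -6.15 ± 1.04, adjusted p = 0.0140, †0.0695), and the galectin Lgals1 -1.80 and 1.246 (difference -3.05 ± 0.52, adjusted p = 0.0140, †0.0695). Slc16a11 gave -1.36 and 5.61 (difference -6.97 ± 1.24, adjusted p = 0.0166, †0.0695), and Fcer1a did not pass (-4.51 ± 0.96, adjusted p = 0.0524). In the interferon list 5 of 48 members passed (24 for the list alone), with a median of 1.247 (adjusted p = 1.64e-15, estimated 0.251). In the dendritic list 0 of 21 passed (16 for the list alone), with a median of 3.53 (adjusted p = 2.46e-08, estimated 0.416). Stem cell genes had a median of 1.60 (adjusted p = 4.10e-09, estimated 0.251). Of 27 genes that passed, 24 were higher and 3 lower. The count was 1 without V3, 0 without V3-2 and 644 without V9, so none of these calls outlasted every library left out.

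Across comparisons, few list calls held with an estimated correlation. They were B-cell genes in IDH2-FLT3 vehicle, TET2-FLT3 vehicle, AG-221 and 5-Aza against WT, megakaryocyte and erythroid genes in TET2-FLT3 vehicle and AG-221 against WT, and imprinted genes in TET2-FLT3 vehicle against WT. A rotation test (fry) asks whether the genes of a list moved together without reference to other genes. It gave a false discovery rate of 0.00432 for stem cell genes and 0.0415 for granulocyte-monocyte genes with AG-221. With 5-Aza it gave 0.00379 for interferon and 0.0258 for dendritic cell genes. Lists called in no pair of groups were endothelial and stromal genes (median -1.89 in IDH2-FLT3 vehicle against WT, adjusted p = 0.133), DNA methylation machinery, p53 targets and heme genes (median 0.29, adjusted p = 0.208). Reads of genes with several accessions were in part not counted, so Dnmt1 could not be measured. Near-identical paralogs or overlapping genes such as H2 chains, Vpreb3 and Kcnq1ot1 carry a like uncertainty, as the strand setting is not stated.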

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

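The tests without V3-2 and V5-2, of other cell types, of MHC class II genes with a dendritic score and of the neighbors of Tet2 were chosen after the results they concern were seen, and the other tests in this part before. Stem cell genes were higher and granulocyte-monocyte genes lower with AG-221, which may reflect the vehicle library that stands apart, sequence composition, the mix of sorted cells or a change within stem cells. Without V3-2 and V5-2 the stem cell and granulocyte-monocyte medians were 1.04 and -1.32 (adjusted p = 3.28e-05 and 6.40e-05). A GC and length correction gave 1.65 (adjusted p = 1.01e-07) and -2.001. The signs held, but 0 lists were called at an estimated correlation with all libraries, leaving both causes open. If a smaller share of granulocyte-monocyte cells alone lay behind the pattern, the other cell types would have risen alike. The highest and the lowest of their medians, of erythroid and mast cell genes, differed by 2.54 (standard error 0.618). That pair was picked for its extremes and the standard error takes genes as independent, so the test cannot decide this. Its stem cell part rests mostly on V3 and V3-2, whose stem cell scores against WT of -3.54 and -3.80 lay far from -1.15 in V9 and -0.92 to -0.85 with AG-221, so 1 animal behind both libraries remains possible, and other changes in the mix of cells were not tested.

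Interferon and MHC class II genes were lower with 5-Aza, which may reflect a single library, fewer dendritic cells among the sorted cells, or a drug response within the cells. The weakest interferon median with 1 of the 8 libraries left out was -0.69, so no single library accounts for it, but with 2 of the 4 vehicle libraries it ran from -1.31 to -0.23, and V5 and V5-2, which held the highest scores, could be 1 animal. With a dendritic cell score as a covariate the interferon median went from -0.86 to -0.54 (adjusted p = 5.80e-05). That of MHC class II genes went from -2.01 to -0.27 (adjusted p = 0.153). These p-values use the preset correlation, and without the score 0 lists were called with an estimated one. With the score 14 genes were called, against 222 without it. The score separated the arms, at 0.43 to 1.26 in TET2-FLT3 vehicle and -2.43 to -0.60 with 5-Aza. A rough score can also leave part of such a difference in place, so the test does not decide. For both lists a smaller share of dendritic cells thus remains possible.

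Genes near Tet2 that differ between the leukemia lines in both arms, such as Ifi44, Ifi44l and Vcam1, may reflect variants carried along with the engineered locus or a biological difference of the lines, which was not tested. Without interferon genes 13 of 160 neighbors (8.13%) were called, a share met in 0.661% of windows, overlapping ones included. Variants carried with Tet2 would set the TET2-FLT3 line apart from WT, but in 12 of the 16 called neighbors, Ifi44 and Ifi44l among them, IDH2-FLT3 lay further from WT, as in 371 of all 498 genes called between the lines, so the test does not tell whether such variants play a part. Of the 490 genes called between the lines that have a known position, 5.51% lay near Idh2, Flt3 or Tet2, where 4.31% of all tested genes lie, which does not account for the line difference as a whole.

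Other splits of the same libraries tested whether chance can be excluded. For gene counts, 1 of 35 splits gave as many calls as the real one in IDH2-FLT3 vehicle against WT (2428 calls, highest other 216), 1 of 35 in TET2-FLT3 vehicle against WT (1199, 0), 1 of 35 for AG-221 (1145, 105), 1 of 35 for 5-Aza (222, 1), 1 of 35 for AG-221 against WT (321, 0) and 1 of 35 for 5-Aza against WT (203, 0), so chance can be excluded there. If V3 and V3-2 were 1 animal, IDH2-FLT3 vehicle would leave too few splits against WT or AG-221 for a share under 0.05, so the exclusion in those 2 comparisons holds only if they are separate. Between the leukemia lines chance cannot, with 7 of 35 splits at 506 calls or more (highest other 2268). For the difference of drug responses 4 of 100 random splits reached 27 calls, close to the limit of 0.05. The split with 2333 calls kept the AG-221 libraries together, so splits cannot tell if responses differ. The split between the lines with 2268 calls put V3, V3-2 and V5-2 together, which points to a structure of these libraries beyond their groups. For list counts chance stays open: even TET2-FLT3 vehicle against WT (1 of 35, 22 lists) had 21 in another split. Elsewhere as many lists were called in 5, 9, 2, 7, 2 and 8 of 35 splits for IDH2-FLT3 against WT, AG-221, 5-Aza, AG-221 against WT, 5-Aza against WT and the 2 lines (20, 14, 16, 17, 17 and 15 lists; highest others 21, 19, 17, 21, 17 and 17), and in 27 of 100 for the difference of drug responses (12 lists, highest other 18).

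Drug responses differed by an interaction test in 27 genes and 12 lists. With an estimated correlation 0 lists passed, and without V3 and V3-2 1 and 0 genes. Each drug had 1 line, so drug and line cannot be separated. Differences were 3.52 (Ifit1), 4.02 (Ifi44), 4.25 (Ldhd), 5.11 (Ccl3), -6.15 (Cdr2), -3.05 (Lgals1) and -6.97 (Slc16a11). One library lay far from the other 3 of its group, by Dixon's 95% critical value for 4 samples, in 20 of 278 tested pairs of a printed gene and a group; chance flags about 1 in 20 groups. In WT these were Thy1 at 15.3 CPM in wt1 (others 8.59 to 9.68), Etv5 at 31.6 CPM in wt3 (others 17.5 to 19.7) and Pim2 at 34.6 CPM in wt1 (others 23.4 to 24.6). With AG-221 they were Id1 at 72.8 CPM in AG1 (others 48.3 to 51.9), Itgae at 153 CPM in AG13 (others 6.85 to 10.0), Tespa1 at 241 CPM in AG8 (others 138 to 149), Prtn3 at 2013 CPM in AG12 (others 1149 to 1255), Adgre1 at 16.5 CPM in AG13 (others 8.71 to 9.94), Rpl36 at 90.0 CPM in AG13 (others 49.1 to 50.4) and Slc16a11 at 1.01 CPM in AG1 (others 0 to 0.154). In TET2-FLT3 vehicle they were Id1 at 27.3 CPM in V5-2 (others 47.4 to 50.4), Thy1 at 45.9 CPM in V5 (others 175 to 192), Hspa8 at 1183 CPM in V1 (others 394 to 413), Rhd at 3.17 CPM in V19 (others 0.246 to 0.682), Manf at 659 CPM in V1 (others 202 to 258) and Epx at 6.004 CPM in V1 (others 0.205 to 0.576). With 5-Aza they were Cd79a at 6.07 CPM in AZ16 (others 0.486 to 1.35), Slfn1 at 2.02 CPM in AZ11 (others 0.451 to 0.683), Atf3 at 0.405 CPM in AZ11 (others 0 to 0) and Cks2 at 63.7 CPM in AZ17 (others 39.0 to 42.8).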

How the results depend on the processing

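The 3 settings about V3-2 and V5-2 were chosen after the data were seen, and the other tests were planned. No called printed gene reversed direction under any setting, while some estimates of uncalled genes changed sign. Of 233 printed gene results 223 kept their side of the threshold with DESeq2, 229 with RLE factors, 224 without a filter, 202 with limma-voom, 212 and 219 with FPKM plus 1 and plus 0.1, and 207, 222 and 204 with V3-2 and V5-2 left out, marked by a covariate, or summed with V3 and V5. With the stricter filter 5 of 228 lost and 2 gained a call, and fits of the compared groups alone kept 165 of 230. In IDH2-FLT3 against WT, TET2-FLT3 against WT, AG-221 and 5-Aza, 34, 30, 11 and 16 of the called printed genes kept their calls with each library left out, and 33, 31, 0 and 16 under all the other settings. No paired analysis was possible because the columns of the treated and vehicle libraries carry no replicate numbers. Fits that leave 2 libraries in an arm rest on the spread of all groups, and with 3 or 4 libraries a 2-fold change was rarely found.

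Counts that moved by over 1.5 times are given by setting, and the cause was not tested. DESeq2 called 1928 genes in TET2-FLT3 against WT, 2108 with AG-221, 462 with 5-Aza, 589 in AG-221 against WT, 635 in 5-Aza against WT, 1150 between the lines, 364 for the difference of drug responses and 1127 shared against WT. The limma-voom counts were 1832 with AG-221, 2131 and 2755 for AG-221 and 5-Aza against WT, 192 between the lines and 92 for the difference. Fits of the compared groups alone gave 0 with AG-221, 823 and 2157 for AG-221 and 5-Aza against WT, 17 between the lines and 0 for the difference (1388 genes with an unadjusted p under 0.05). From FPKM plus 1 the counts were 1884 for TET2-FLT3, 655 for AG-221 and 844 for 5-Aza against WT and 45 for the difference, and from FPKM plus 0.1 508 and 560 for AG-221 and 5-Aza against WT and 98 for the difference. FPKM values moved the all-gene median to -0.20 in IDH2-FLT3 against WT (counts 0.02), -0.18 in TET2-FLT3 against WT (counts 0.07) and 0.07 with AG-221. A correction for GC content and length gave 527 higher and 199 lower genes in 5-Aza against WT, 419 genes in AG-221 against WT with 198 of them lower, and 362 and 411 between the lines. The difference count was 185 without a filter and 44 with the stricter one. Without V3-2 and V5-2 the counts were 265 with AG-221, 443 for 5-Aza against WT and 187 between the lines, and 9 lists with 5-Aza; with a covariate for these libraries they were 620, 482, 782 and 10 lists, and 80 for the difference. Summing them with V3 and V5 gave 1599 in IDH2-FLT3 against WT, 197 with AG-221, 149 between the lines and 14 for the difference. Of TET2-FLT3 calls, 66.96%, 70.1% and 71.1% were opposite under AG-221 in these 3 settings and 93.8% under 5-Aza when summed, and 72.0% of IDH2-FLT3 calls were opposite under 5-Aza without V3-2 and V5-2. With an estimated correlation 1, 4, 0, 0, 3, 1 and 0 lists were called in the 7 pairs of groups in the order of the report.

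Leaving out 1 library at a time gave from 1266 to 2779 genes in IDH2-FLT3 against WT, 503 to 1410 in TET2-FLT3 against WT, 97 to 2252 with AG-221, 57 to 241 with 5-Aza, 170 to 289 in AG-221 against WT, 73 to 139 in 5-Aza against WT, 114 to 1656 between the lines and 0 to 644 for the difference. Lists called ranged over 9 to 17 with 5-Aza and shared calls over 324 to 865. The opposite shares ranged over 94.7 to 98.1% (IDH2-FLT3, AG-221), 90.0 to 95.4% (TET2-FLT3, 5-Aza), 63.3 to 81.1% (TET2-FLT3, AG-221) and 64.7 to 81.4% (IDH2-FLT3, 5-Aza).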

Other observations

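The test between the lines over both arms was chosen before its result was seen, and the genes named here after. Between the leukemia lines, vehicle and drug arms together, Mtmr9 and the ubiquitin ligase gene Ccnb1ip1 stood out. Mtmr9 read 66.4 ± 7.04 CPM in WT, 40.2 ± 9.55 in IDH2-FLT3 vehicle, 21.9 ± 1.76 with AG-221, 392 ± 139.5 in TET2-FLT3 vehicle and 280.2 ± 37.4 with 5-Aza (log2 difference of the lines -3.48, adjusted p = 6.93e-10). Ccnb1ip1 read 16.3 ± 12.98, 0.0160 ± 0.0278, 0.165 ± 0.106, 25.2 ± 12.8 and 34.1 ± 6.96 CPM in the same order (-8.66, adjusted p = 5.37e-09), and Adgrl4, an adhesion receptor of endothelial and stem cells, 948 ± 126, 134 ± 38.7, 176 ± 30.3, 373 ± 46.0 and 633 ± 148 (-1.66, adjusted p = 1.33e-05).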
